A study of Rattus norvegicus with 12 samples.

How the data were processed

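RNA was measured in 3 clones of INS1E, a rat pancreatic beta-cell line that secretes insulin. One clone carried the empty expression vector pcDNA3 and served as the control, one was stably transfected with human islet amyloid polypeptide (hIAPP) and one with the rat form (rIAPP). Per the labels, cells grew in medium with 11.1 mM glucose and were collected after 3 days, and biotin-labelled target from total RNA was hybridised to 1-colour Affymetrix rat gene arrays. Each clone was measured in 2 samples, lettered a and b, on 6 arrays in all. The design text counts 6 samples from 3 clones, so clone and transgene cannot be told apart, and the p-values measure only the spread between samples of 1 clone. Whether a and b were separate cultures is not given in the sources used here.

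The authors deposited each array as log2 values at gene level, with 36685 transcript clusters, and at exon level, with 220231 probe sets. Per the submitters' processing notes these came from Affymetrix Expression Console and RMA, whose versions are not given in the sources used here. RMA corrects background, normalises by quantiles and summarises probes. The values were used as deposited. The 2 levels come from the same arrays and are not further replicates. A table of gene names for the platform gave exactly 1 symbol for 18511 gene-level transcript clusters, several for 575 and none for 17599. Only those with 1 symbol were used, and for a symbol with several the one with the highest mean was kept, which left 18166 genes. At exon level 166557 probe sets had 1 symbol, and 2845 older symbols were updated through synonyms that pointed to a single gene in the GRCr8 annotation. The array's build is not given in the sources used here, so no coordinates are printed and the annotation served only for names and for which genes neighbour each other. Of the 18166 genes, 18124 were placed on a chromosome.

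Group means were fitted with limma 3.58.1 in R 4.3.3 to all 6 arrays, which share 1 estimate of the spread with 3 residual degrees of freedom and 4.39 prior ones. The contrasts were hIAPP minus control, rIAPP minus control and hIAPP minus rIAPP. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p below are from this moderated test unless another is named. Genes called against control in a clone, and also between the clones in the matching direction, were counted as specific to that clone. A call in the other clone did not exclude a gene, so genes called in opposite directions could count for both. The 2 contrasts against control share their control arrays, so the correlation and covariance of their log2 differences were set beside 100 simulations of unchanged groups. Their overlap was set beside that of independent lists.

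Gene lists were fixed before the data were examined, 32 in all, with 734 of 849 listed genes measured. They were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a contrast. The same test with an estimated correlation and the fry test were run beside it. Genes named below follow a rule also fixed before the data were examined. It takes Iapp, and in each contrast the 10 largest rises and 10 largest falls among called genes whose samples did not overlap between the groups, whose higher group mean was at or above the median of all genes and whose symbol is no predicted locus, small RNA or olfactory or vomeronasal receptor. It adds, per list, up to 4 called members by size of difference, 8 genes called in the same direction and 8 in opposite directions in both clones, and 6 genes per contrast for exon use. Exon use was tested with limma's diffSplice F test on probe sets at or above the median level, in genes with at least 4 of them, which gave 86763 probe sets in 7982 genes.

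For neighbouring genes, a running median over 51 genes at or above the median level was taken along each chromosome and compared with the highest value in each of 1000 shuffles of the gene order. This step was chosen after the data were examined.

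Each procedure was tested on simulated data with the measured means and spreads. For hIAPP against control, with 50 changed genes per size among 18166, limma recovered 34% of changes of 0.25 on the log2 scale, 98% of changes of 0.5 and 100% of changes of 1. Over 20 draws 7.57% of its calls were false. With 1 list shifted by 0.25 in genes simulated as independent, camera called that list at the preset correlation (adjusted p = 1.77e-43) and with an estimated one (adjusted p = 0.0181), and 0 other lists at the preset correlation. With a run of 100 neighbouring genes shifted by 0.25, the running median passed its threshold at all 100 and at 20 genes outside the run. The exon test made more false calls. With 1 probe set shifted by 1 in 200 of 7982 genes it recovered 179.25 genes on average and also called 60.75 unchanged ones, so that 25.3% of calls were false against the nominal 5%. With equal spread of the probe sets of a gene the share was 4.54%, so the excess came with unequal spread of probe sets within a gene. The test had been fixed before the data were examined and was kept. At an adjusted p under 0.001 the false share was 7.19%, and that count is given beside it. Weighting probe sets by their variance and the Simes test gave 39.9% and 54.9% false calls.

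The alternatives were a replicate block by sample letter, fits of only the groups compared, an intensity trend, robust moderation, bright genes alone, repeated quantile normalisation, median centring, gene values as medians of exon-level probe sets, all transcript clusters with a symbol, a minimum change, leaving out each array, and centring on neighbouring genes, which was added after the data were examined, as were the split of the control arrays between the contrasts, the stricter threshold and the variance weights for exon use. Depth does not apply to arrays, whose number limits the precision. The median standard error of a difference was 0.0582 on the log2 scale.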

Results

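The series compared 3 stable clones of the rat beta-cell line INS1E, a control with empty vector, a clone carrying human IAPP and a clone carrying rat IAPP. IAPP, or amylin, is a peptide that beta cells store and secrete with insulin; the human form aggregates into amyloid and the rat form does not. The contrasts ask how each transfected clone differed from the control and from the other. There were 2 samples per clone on 6 arrays. Values correlated across genes at 0.9987 to 0.9990 within a clone and at 0.9934 to 0.9955 between clones (Pearson r; genes are not independent replicates). The median SD between samples of a clone was 0.0406 in the control, 0.0478 in the hIAPP clone and 0.0390 in the rIAPP clone on the log2 scale. Every contrast compares single clones, so differences between clones that have nothing to do with the transgene are part of each value.

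Iapp itself (transcript cluster 17788035) was among the brightest genes, at or above 99.9% of transcript clusters. Its level was 13.74 in the control, 13.81 in the hIAPP clone and 13.91 in the rIAPP clone (means of log2 values, n = 2). The difference from control was 0.06 in the hIAPP clone (SE 0.0469, limma adjusted p = 0.406) and 0.17 in the rIAPP clone (SE 0.0469, limma adjusted p = 0.0507), and neither passed the test. All 4 exon-level probe sets had higher mean values in both transfected clones, by 0.04 to 0.12 in hIAPP and by 0.15 to 0.20 in rIAPP. The limma adjusted p of the rIAPP difference ranged from 0.000429 with an intensity trend to 0.759 after centring on neighbouring genes. In the hIAPP clone Iapp lies in a stretch of chromosome 4 whose genes were higher together, and centring on them gave −0.25 (limma adjusted p = 0.0118). Subtracting a neighbour shift from a signal near the top of the array range gives such a value wherever that signal is compressed, so it cannot be read as a lower level of Iapp, and the 0.759 in rIAPP carries the same doubt.

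In the hIAPP clone genes for protein folding in the endoplasmic reticulum were higher than in the control. Of the 24 measured ER chaperones and folding factors, 13 rose and none fell, with a mean log2 difference of 0.34 (camera adjusted p = 8.69e-09 at the preset correlation and 0.404 with an estimated one). Adjusted over the list alone, 18 rose and 1 fell. Sdf2l1, part of an ER chaperone complex, rose by 1.45 on the log2 scale (SE 0.0542, adjusted p = 7.36e-06), the oxidase Ero1b by 1.28, Creld2 by 0.67 and the chaperone Hyou1 by 0.56. Genes of ER-associated degradation and targets of the transcription factor XBP1 rose too, 10 of 22 with none falling (mean 0.24, camera adjusted p = 4.12e-05, and 0.404 with an estimated correlation; adjusted over the list alone, 11 rose). Derl3, which takes part in moving misfolded proteins out of the ER, rose by 2.00 (SE 0.0664), Herpud1 by 0.50, Sel1l by 0.47 and Edem1 by 0.34.

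ER genes were higher in the rIAPP clone as well. There 16 of the 24 chaperones rose and none fell (mean 0.38, camera adjusted p = 1.69e-11, and 0.349 with an estimated correlation; 20 adjusted over the list alone), and 7 of the 22 degradation genes rose with none falling (mean 0.23, camera adjusted p = 4.53e-05, and 0.349 with an estimated correlation; 7 adjusted over the list alone). Ero1b rose by 1.51, Sdf2l1 by 1.40, Creld2 by 0.70, Hyou1 by 0.62, Derl3 by 1.86 and Edem1 by 0.52. Set against each other, the clones differed over the chaperones by −0.04 on average (hIAPP minus rIAPP, camera adjusted p = 0.661). Adjusted over the list alone 2 were higher and 2 lower, and over all genes 1 of each. Ero1a, a hypoxia-responsive oxidase, differed by −0.50 and Fkbp11 by 0.23. The call of Fkbp11 ended without hIAPP a (adjusted p = 0.0718), hIAPP b (0.139), rIAPP a (0.176) or rIAPP b (0.121), and with medians of exon-level probe sets (0.0875).

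**Figure D1:**
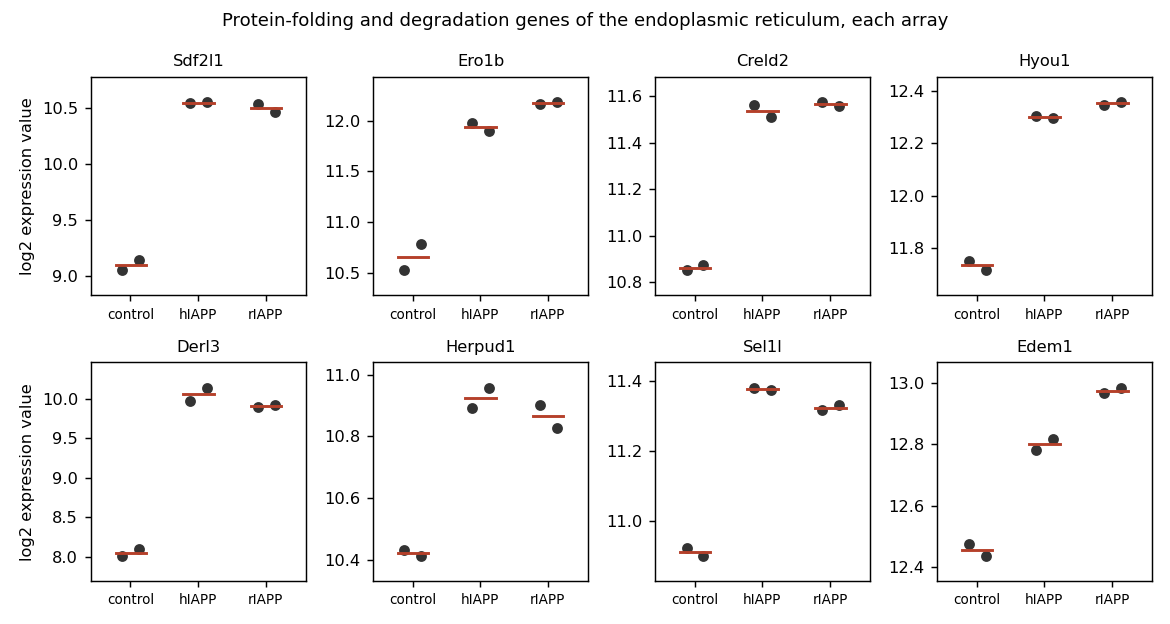
Log2 expression values of 8 ER genes on each of the 6 arrays (points, samples a and b; lines, mean of the 2), with a separate vertical axis per gene that does not start at 0. Both arrays of each transfected clone lie above both control arrays for all 8 genes; Derl3 goes from 8.05 in the control to 10.06 in hIAPP and 9.91 in rIAPP.

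Selenop, a secreted selenium-transport protein, had the largest rise among the genes the rule takes for hIAPP against control, by 3.58 on the log2 scale (SE 0.0786, adjusted p = 1.76e-06), from a mean of 7.64 to 11.22. Other large rises were Tmem35b (2.52), the guanine deaminase Gda (2.47), Zfp40 (2.45), the Notch ligand Jag1 (2.18), the tyrosine kinase gene Frk (2.03), the potassium channel gene Kcnq1 (1.94), Cyp4x1 (1.92) and Klk1b3 (2.02), whose kallikrein family is hard to separate by probes. Dpp10, which associates with potassium channels, fell by 3.25 on the log2 scale (SE 0.0926, adjusted p = 3.1e-06). Log2 differences were −2.97 for the translation factor Eef1a2, −2.91 for Ptgr2, −2.88 for the G protein subunit Gng3, −2.49 for Plch1, −2.37 for the NMDA receptor subunit Grin1, −2.23 for the glucagon receptor Gcgr, −2.15 for Bmp7, −2.01 for Olfml1 and −1.95 for Fetub. Ptgr2 (mean 6.64) and Plch1 (6.23) in hIAPP and Zfp40 in the control (6.09) lay near the arrays' lower quartiles of 6.09 to 6.13, where background was not assessed, so the exact sizes of their differences are uncertain. In total 3462 of 18166 genes were called, 1839 higher and 1623 lower, and 150 of them differed by at least 1. Centring on neighbouring genes moved the 20 genes taken by size by at most 0.105. Differences this large could hardly lose their calls that way, and all 20 kept theirs. Leaving out control a gave 2001 genes and leaving out control b 2245, and medians of exon-level probe sets gave 1337.

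Genes of secretory granule cargo fell in the hIAPP clone, 6 of 16 with none rising (mean −0.19, camera adjusted p = 0.00972, and 0.404 with an estimated correlation; adjusted over the list alone, 6 fell). The differences were −1.11 for Qpct, which modifies the ends of peptide hormones, −0.58 for Scg3 and −0.42 for Scg5. Of 36 insulin and IGF signalling genes 11 rose and 1 fell (mean 0.18, camera adjusted p = 0.000683, and 0.404 with an estimated correlation; adjusted over the list alone, 12 and 1), among them Igfbp3 by 1.15, Igf1 by 1.06 and Igf2r by 0.72. Of 30 interferon and antigen presentation genes 9 rose and 1 fell (mean 0.18, camera adjusted p = 0.0192, and 0.404 with an estimated correlation; adjusted over the list alone, 9 and 2), led by the immunoproteasome subunits Psmb8 (1.19) and Psmb9 (0.87) and the peptide transporter Tap1 (0.87). Of 25 cholesterol and fatty-acid synthesis genes 8 rose and none fell (mean 0.16, camera adjusted p = 0.000322, and 0.439 with an estimated correlation; adjusted over the list alone, 9), such as Msmo1 by 0.49 and Hsd17b7 by 0.48. Without control b the granule list had a camera adjusted p of 0.0554 (range over its alternatives 0.000348 to 0.0554), and without hIAPP b the interferon list had 0.0704 (range 0.00776 to 0.0704); on bright genes alone the interferon mean was 0.39.

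Genes of beta-cell identity moved both ways. In the hIAPP clone 7 of 23 rose and 8 fell (adjusted over the list alone, 8 and 9; camera adjusted p = 0.799), and the list's mean of 0.07 and its test pointed up while its median was −0.02. Ucn3, a marker of mature beta cells, rose by 1.41 and the granuphilin gene Sytl4 by 0.92. In the rIAPP clone 8 rose and 4 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.162), and Ins1 fell by 0.51. The fry test called the list upwards in rIAPP (fry adjusted p = 0.0274) but did not call it in hIAPP (fry adjusted p = 0.0796). Ins2 differed by −0.74 in hIAPP (adjusted p = 0.0131) and −0.64 in rIAPP (adjusted p = 0.0269). These calls ended without control a (adjusted p = 0.0818 and 0.139) and with medians of exon-level probe sets (0.157 and 0.286), in hIAPP also without hIAPP a (0.0615), and in rIAPP also without control b (0.0537) or rIAPP b (0.158).

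Several other groups held large single changes without a camera call for the list. The fry test did call the apoptosis list (fry adjusted p = 0.00601 in hIAPP and 0.00515 in rIAPP). In hIAPP it also called exocytosis (fry adjusted p = 0.0176) and immediate-early genes (fry adjusted p = 0.0215). It did not call those lists in rIAPP, or the oxidative stress list in either clone. Among 31 genes of exocytosis 7 rose and 8 fell in hIAPP (8 and 9 adjusted over the list alone; camera adjusted p = 0.727) and 6 rose and 5 fell in rIAPP (7 and 6; camera adjusted p = 0.715), with Rab3b at −1.51 and −0.87. Among 32 oxidative stress genes 4 rose and 4 fell in hIAPP (4 and 5 adjusted over the list alone; camera adjusted p = 0.83) and 6 rose and 6 fell in rIAPP (6 and 7; camera adjusted p = 0.81). The quinone reductase Nqo1 rose by 1.49 and 1.26, and Txnip, a thioredoxin inhibitor, differed by −0.92 and −1.02; in both clones this list's mean was positive at 0.02 while its median, at −0.04 and −0.02, and its test pointed down. Among 29 immediate-early genes 3 rose and 7 fell in hIAPP (3 and 8 adjusted over the list alone; camera adjusted p = 0.254), and 3 rose and 7 fell in rIAPP (4 and 8; camera adjusted p = 0.249), with Jun at −1.58, Junb at −0.66 and Egr1 at −0.51 in hIAPP. Of 29 apoptosis and p53 genes 7 rose and 3 fell in hIAPP (9 and 4 adjusted over the list alone; camera adjusted p = 0.175) and 8 rose and 2 fell in rIAPP (11 and 3; camera adjusted p = 0.056), with the survival gene Bcl2 up by 0.52 and 1.12.

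Lists of markers of other cell types were not called against control. Of 12 alpha, delta, PP and epsilon cell markers Gcg (0.17) was higher and Etv1 (−0.20) lower in hIAPP (1 and 1 adjusted over the list alone; camera adjusted p = 0.727). In rIAPP Fev (−0.61) and Etv1 (−0.23) were lower (2 adjusted over the list alone; camera adjusted p = 0.514). The calls of Gcg and Etv1 ended when any array of the groups compared was left out, and that of Fev with medians of exon-level probe sets (adjusted p = 0.0504). Of 20 acinar and ductal markers none passed the test in hIAPP (0 adjusted over the list alone; mean −0.03, camera adjusted p = 0.727). In rIAPP their mean was −0.10 and their median −0.12 (camera adjusted p = 0.0804, fry adjusted p = 0.015). There 1 of them, Bhlha15 at 0.21, was called higher (1 adjusted over the list alone), but not without control a (adjusted p = 0.12), control b (0.0707), rIAPP a (0.121) or rIAPP b (0.098). Of 21 macrophage and leukocyte markers 3 were higher in each clone and none lower, Cd4 by 0.78 and 0.70 (3 adjusted over the list alone in each; camera adjusted p = 0.727 and 0.715), though the list's mean of 0.04 and its median, −0.01 in hIAPP and −0.03 in rIAPP, differed in sign. Of 14 fibroblast and endothelial markers 1 was higher and 1 lower in each, with Thy1 at −0.46 and −0.69 (1 and 1 adjusted over the list alone in each; camera adjusted p = 0.356 and 0.228).

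**Figure D2:**
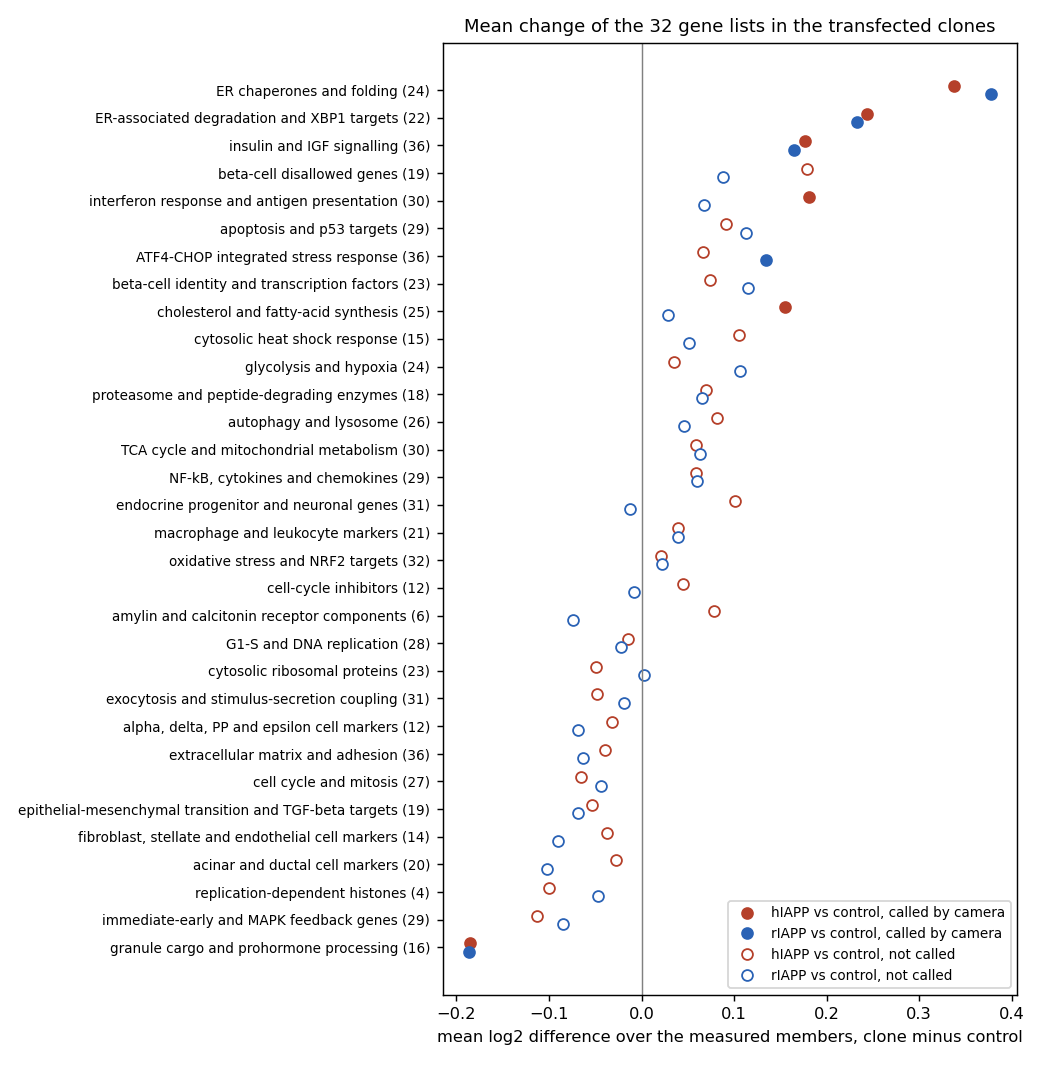
Mean log2 difference from the control over the measured members (number in brackets) of each of the 32 gene lists, in the hIAPP and rIAPP clones; filled points were called by camera at a preset correlation of 0.01. ER chaperones lie farthest to the right at 0.34 and 0.38, and granule cargo farthest to the left at −0.19 in both clones.

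Gnat3, the G protein of taste receptor signalling, fell by 5.97 on the log2 scale between the control and the rIAPP clone (SE 0.0839, adjusted p = 1.7e-07), from a mean of 12.33 to 6.36. The lower level is close to the arrays' lower quartiles of 6.09 to 6.13, where background was not assessed, so the exact size of this difference is uncertain. Log2 differences were −2.76 for Cyp2c55, −2.56 for Dpp10, −2.43 for Gcgr, −2.16 for Dpysl3, −1.98 for Olfml1, −1.97 for Elmod1, −1.79 for the synaptic vesicle protein Sv2c, −1.75 for the cation channel gene Trpc4 and −1.68 for Plppr3. Crispld1 rose by 2.93 (SE 0.0539, adjusted p = 4.46e-07), the decoy receptor Tnfrsf11b by 2.70, the cadherin Cdh7 by 2.37, the insulin receptor-related receptor Insrr by 2.19, Itpkb by 2.11, Tmem176a by 2.04, the neurotrophin receptor Ngfr by 2.00 and Car8 by 1.76; the control mean of Insrr, 6.48, was also close to those quartiles. In total 2908 genes were called, 1581 higher and 1327 lower, 108 of them by at least 1. Centring on neighbouring genes moved the 20 genes taken by size by at most 0.201. Here too their differences were too large for that to end a call, and all 20 kept theirs. Leaving out control a gave 1364 genes, control b 1658, rIAPP a 1342 and rIAPP b 1224, and medians of exon-level probe sets gave 953.

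The integrated stress response, whose genes respond to ATF4 and CHOP, was called in the rIAPP clone. Of 36 members 9 rose and 1 fell (mean 0.13, camera adjusted p = 0.000542; adjusted over the list alone, 11 and 1; camera adjusted p = 0.349 with an estimated correlation), including Vldlr by 0.71 and Ddit4 by 0.59. In the hIAPP clone 10 rose and 5 fell (10 and 6 adjusted over the list alone, mean 0.07, camera adjusted p = 0.175, fry adjusted p = 0.00601). The difference between the clones was not called by camera (mean −0.07, camera adjusted p = 0.308, fry adjusted p = 0.0221). Insulin and IGF genes in rIAPP gave 9 higher and 2 lower of 36 (mean 0.165, camera adjusted p = 0.00553, and 0.371 with an estimated correlation; adjusted over the list alone, 11 and 2). Igfbp5 rose by 1.51 and Igf1 by 1.32, and the insulin receptor Insr fell by 0.76. Granule cargo had 3 of 16 lower and none higher (mean −0.19, camera adjusted p = 0.00553, and 0.371 with an estimated correlation; adjusted over the list alone, 7 lower), with Qpct at −0.88, Chgb at −0.64 and Scg5 at −0.51. The IGF list was not called on bright genes alone or with medians of exon-level probe sets (camera adjusted p over its alternatives 0.00217 to 0.0724).

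Of the genes called against control, 1605 moved in the same direction in both transfected clones, 883 up and 722 down. Largest in both were falls of Dpp10, Gcgr, Olfml1 and Sv2c and rises of Derl3, Frk, Ngfr and Tnfrsf11b; Frk rose by 2.03 and 1.86, and Sv2c differed from control by −1.81 and −1.79. In opposite directions 88 were called, among them the growth factor gene Tgfb2 at 1.07 and −1.17 and Selenop at 3.58 and −0.86. Independent lists of these sizes would share 279 genes in the same direction and 276 in opposite ones. The log2 differences correlated across genes at r = 0.616, against 0.50 simulated from shared controls alone, and genes are not independent replicates. Their covariance was 0.0320 against a simulated 0.00220, a difference of 0.0298. With 1 control array set against each clone, so that no array was shared, the covariance was 0.0291 or 0.0292 by the array chosen and r was 0.532 or 0.534. Then 745 or 760 genes were shared, against 84.2 or 91.3 for independent lists. This split was chosen after the data were examined. Both control arrays come from 1 clone, and splitting them leaves the state of that clone in both contrasts. Neither the independent lists nor the simulation of unchanged groups allows for differences between clones. The overlap, the correlation and the covariance therefore cannot show a response shared by the transfected clones. Without control a 781 genes were shared, without control b 938, without rIAPP a 851 and without rIAPP b 801, and medians of exon-level probe sets gave 507.

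**Figure D3:**
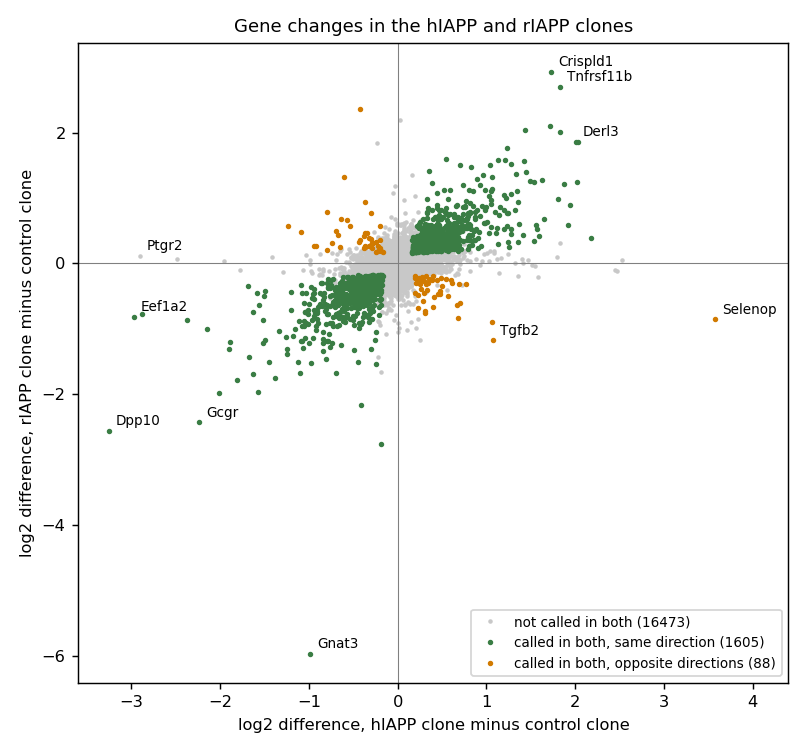
Log2 difference from the control of each of 18166 genes in the hIAPP clone (horizontal) and the rIAPP clone (vertical); green points were called in both in the same direction (1605) and orange points in opposite directions (88). Dpp10 and Gcgr lie low in both clones, Gnat3 lies at −0.98 in hIAPP and −5.97 in rIAPP, and Selenop lies at 3.58 and −0.86.

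Set directly against each other, the clones differed in Gnat3, higher in hIAPP by 4.99 (SE 0.0839, adjusted p = 4.71e-07), and in Selenop, higher by 4.43. The sizes for Gnat3, Zfp40, Tgfb2, Ptgr2, Plch1 and Insrr, each with a mean between 5.99 and 6.64 in 1 clone, carry the same uncertainty of background. Gda (2.59), Cyp2c55 (2.57), Zfp40 (2.55), Tmem35b (2.47), Tgfb2 (2.24), Plac8 (1.96), Pdgfc (1.79) and Jag1 (1.79) were also higher in hIAPP. The differences were −3.02 for Ptgr2, −2.79 for Cdh7, −2.56 for Plch1, −2.16 for Eef1a2, −2.16 for Insrr, −2.10 for Gng3, −1.99 for Fetub, −1.93 for the GABA receptor subunit Gabre, −1.81 for Ppp1r17 and −1.58 for Pcdhb12. In total 2120 genes were called, 1110 higher and 1010 lower in hIAPP, 94 of them by at least 1. Without hIAPP a 1387 genes were called, without hIAPP b 1266, without rIAPP a 935 and without rIAPP b 923, and medians of exon-level probe sets gave 529.

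By this direct test 1158 genes were specific to hIAPP, 626 higher and 532 lower, and 733 were specific to rIAPP, 351 higher and 382 lower. These counts do not exclude genes that were also called in the other clone. Selenop, called in opposite directions against control, counts for both. With an intensity trend 1641 genes were specific to hIAPP and 1137 to rIAPP. After centring on neighbouring genes, a step chosen after the data were examined, 909 and 640 were specific. Of the 25 cholesterol and fatty-acid synthesis genes 7 were higher and 1 lower in hIAPP than in rIAPP (mean 0.13, camera adjusted p = 0.00451, and 0.785 with an estimated correlation; adjusted over the list alone, 10 and 1), with Hsd17b7 at 0.54 and Fdft1 at 0.39. Of the 30 interferon genes 4 were higher and none lower (mean 0.11, camera adjusted p = 0.00549, and 0.785 with an estimated correlation; adjusted over the list alone, 7), such as Ifih1 at 0.59 and Mx1 at 0.41, the latter at a low level of 6.12 and 5.71. Without hIAPP b the interferon list had a camera adjusted p of 0.0549 (range over its alternatives 0.0026 to 0.0549). With medians of exon-level probe sets the calls of Fdft1 (adjusted p = 0.0502) and Ifih1 (0.0594) ended, the interferon mean was 0.18, and 292 and 168 genes were specific. The hIAPP-specific count was 769 without hIAPP a, 749 without hIAPP b, 575 without rIAPP a and 559 without rIAPP b, and the rIAPP-specific count was 430 without control a, 466 without control b, 476 without hIAPP b, 299 without rIAPP a and 297 without rIAPP b.

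At exon level, probe sets of Dlg2, a synaptic scaffold protein, moved in opposite directions within the gene. Of 15 probe sets 9 had higher values in both transfected clones than in the control, by 0.65 on average in hIAPP and 0.90 in rIAPP, and 6 had lower ones, by −0.68 and −0.75 (diffSplice adjusted p = 9.27e-18 and 9.59e-22). The gene-level differences of Dlg2 were −0.42 and −0.23. The medians over these probe sets were 0.49 and 0.76, so its direction as a whole depends on the summary. All 16 probe sets of Grin1 were lower in hIAPP than in control, from −3.44 to −1.37, so there the test found unequal falls. Other genes with the smallest p were Sh2d3c, Ngfr, Trpm2 and Dnajc6 in hIAPP and Trpm5, Sdk2, Gpsm1, Col27a1 and Ngfr in rIAPP. Between the clones they were Grin1, Trpm5, Eef1a2, Rem2, Sh2d3c and Sdk2. In total 696 genes were called in hIAPP, 624 in rIAPP and 80 between the clones. Without the filter on dim probe sets 273 were called between the clones, and with a replicate block 399 in rIAPP. The Simes test called 1067 in rIAPP and 195 between the clones. Calls were more frequent among genes whose gene-level difference was at least 0.5, 38.7% against 7.02% of the others in hIAPP, 32.8% against 6.70% in rIAPP and 15.1% against 0.578% between the clones; a call there can be an unequal change of the whole gene, as in Grin1. On simulated data for hIAPP against control, with 200 changed genes and the measured spread, 25.3% of the test's calls were false; the share in the real counts, which depends on how many genes change and by how much, is not known. At an adjusted p under 0.001, where 7.19% were false in that simulation, 121, 95 and 29 were called. With 1 array left out, the counts against control depended on which array of a clone it was. Leaving out the other array of that clone lowered them less or not at all. Without control a the hIAPP count was 179 and the rIAPP count 169, without hIAPP a the hIAPP count was 286, and without rIAPP b the rIAPP count was 96; between the clones the count was 184 without hIAPP a, 49 without hIAPP b, 188 without rIAPP a and 48 without rIAPP b.

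**Figure D4:**
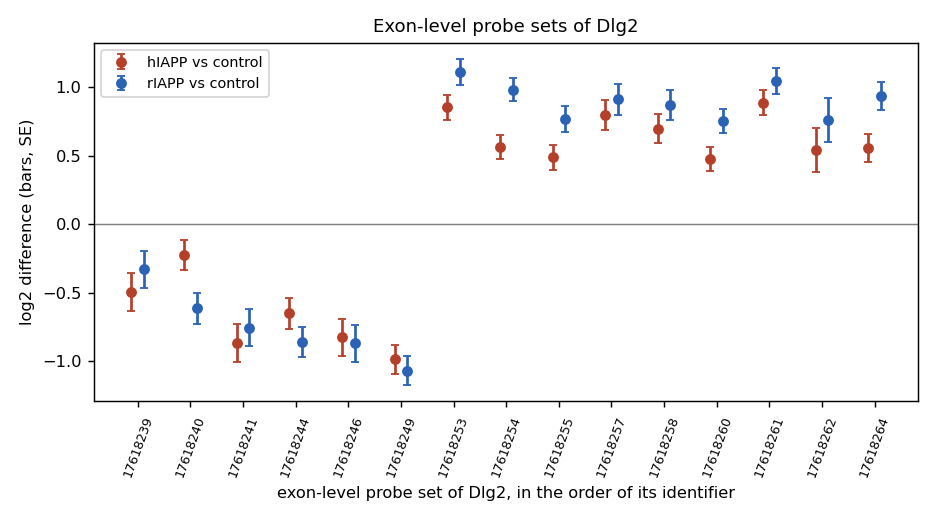
Log2 difference from the control (points) with its SE (bars) for the 15 exon-level probe sets of Dlg2, in the order of their identifiers, in the hIAPP and rIAPP clones. The first 6 lie below 0 and the other 9 above 0 in both clones; where they lie in the gene was not analysed here.

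Neighbouring genes moved together in some stretches of chromosomes (gene order from the rat reference annotation). In the hIAPP clone the 275 well-expressed genes placed on chromosome 16 had a median difference of 0.26 from control, and 91.3% of them lay above the genome median. Medians were also positive over Polr2sl1 to Mios (0.31) and Lhfpl4 to Rimklbl1 (0.27) on chromosome 4, Mrpl30 to Ndufs1 on chromosome 9 (0.28), and Mfsd14b to Fam193b (0.20) and Nsd1 to Sox4 (0.22) on chromosome 17. They were negative over Dsel to Ccdc93 on chromosome 13 (−0.34), Idua to Cox18 on chromosome 14 (−0.28) and Hfe to Lyst on chromosome 17 (−0.16). In the rIAPP clone the 231 genes on chromosome 18 had a median of −0.21, with 92.6% below the genome median, and medians were negative over Zkscan8 to Lyst on chromosome 17 (−0.17) and Insm1 to Hm13 on chromosome 3 (−0.11). Zkscan8 to Lyst lies within the hIAPP stretch Hfe to Lyst. The only stretch of chromosome 17 found between the transfected clones was Mfsd14b to Gpld1 (0.26). Over Zkscan8 to Lyst, a high control clone and a fall in both transfected clones cannot be told apart. Stretches past the shuffling threshold held 21.3% of the placed called genes in hIAPP, 7.03% in rIAPP and 30.2% between the clones. The same stretches held 9.67%, 3.93% and 12.2% of all placed genes. They were found from the same log2 differences, so calls are frequent in them by construction. After centring on neighbouring genes 2642 of the 3462 genes called in hIAPP were called in the same direction and 1 in the opposite one, 2170 of 2908 in rIAPP and 1366 of 2120 between the clones. The neighbour step was chosen after the data were examined.

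**Figure D5:**
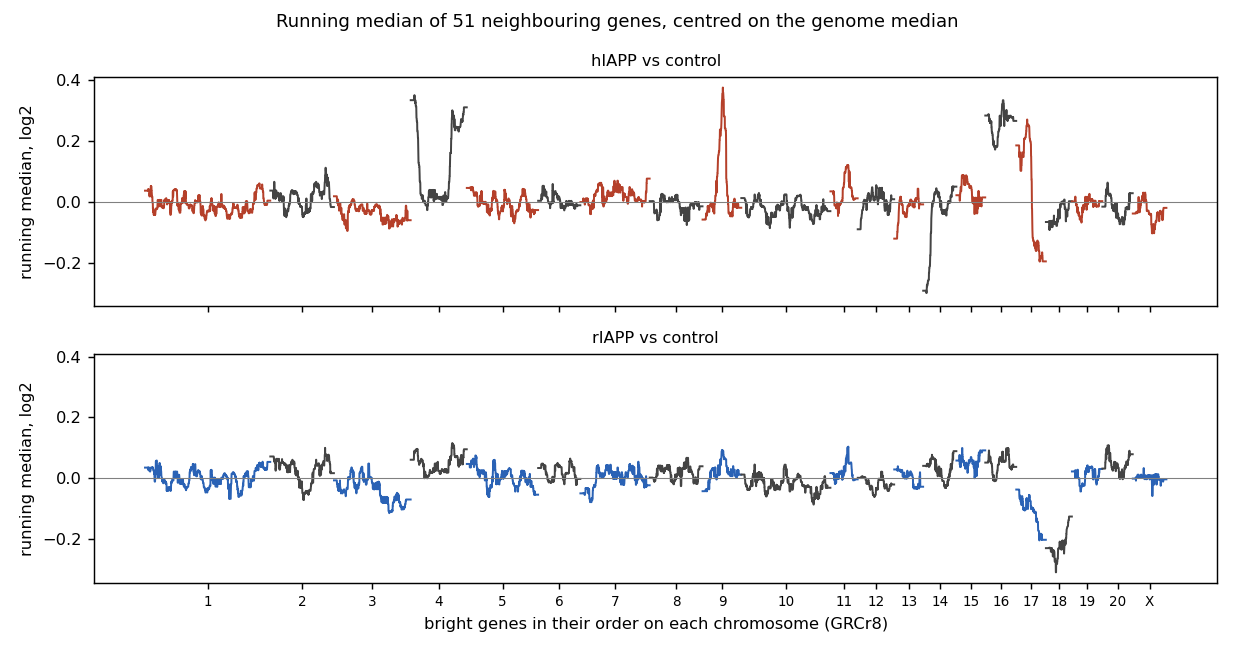
Running median, on the log2 scale, over 51 neighbouring well-expressed genes along each chromosome, centred on the genome median, for each transfected clone against the control; colours alternate between chromosomes. Chromosome 16 and parts of chromosomes 4, 9, 13, 14 and 17 depart from 0 in hIAPP, and chromosome 18 and part of chromosome 17 depart in rIAPP.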

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

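The tests of explanations for the 3 patterns below were chosen only after the result was seen, though the fits without 1 array, the estimated correlation and the contrast of hIAPP with rIAPP were planned. What drew attention was a difference between the clones in their contrast with control, tested directly as hIAPP minus rIAPP. The interferon and antigen presentation list differed by 0.114 and the cholesterol and fatty-acid synthesis list by 0.127 on average, and camera called both at the preset correlation; with an estimated correlation both had a camera adjusted p = 0.785, and without hIAPP b the interferon list had 0.0549. Among genes that went opposite ways against control, Selenop differed by 4.43, Tgfb2 by 2.24, Plac8 by 1.96, Pitpnc1 by 1.52 and Pxt1 by 1.31, and Gabre by −1.93, Pcdhb12 by −1.58 and Copz2 by −1.32. These genes were picked for large opposite differences from control, and hIAPP minus rIAPP is the difference of those 2 contrasts. Their large values here follow from that choice and are no further test.

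Runs of neighbouring genes were shifted together between the clones. The chance order of genes does not account for them, since the highest running median in hIAPP was 0.375 against a threshold of 0.117 from shuffled orders. In the 12 runs of at least 20 genes against control error between arrays does not either, since the samples of a clone differed by at most 0.264 of the run's shift, but in 6 of the 9 shorter runs they differed by at least 0.5 of it (at most 4.35), so there array error stays open; the highest running median between the samples of hIAPP was 0.102. A candidate explanation is a gain or loss of chromosome copies in a clone, which would move nearly all genes of a run, and 91.3% of the genes of chromosome 16 lay on the same side, while over the 12 runs the share ranged from 78.4% (Mfsd14b to Fam193b) to 96.2% (Dsel to Ccdc93). No DNA was analysed here, so joint regulation of neighbours stays open, as does any part of the transgene in it.

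ER chaperone genes were higher in both transfected clones. Shifted neighbours are not the whole cause, because the list mean stayed at 0.304 in hIAPP and 0.334 in rIAPP after centring on neighbouring genes and was still called at the preset correlation; without centring camera gave an adjusted p = 0.404 and 0.349 with an estimated correlation. A single array is not the cause either, since the lowest mean without 1 array was 0.323. An effect of either IAPP and a low state of the control clone cannot be told apart, because 1 control clone was measured and both contrasts share it; the transfected clones differed by −0.0406.

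Iapp differed little between the control with empty vector and the clones transfected with human or rat IAPP. Neither difference passed the main test. Signal near the top of the array range may compress its difference, as Iapp lay at or above 99.9% of transcript clusters. That and a small true difference cannot be told apart, since no table here holds a measure of the transgene alone. Whether the rat probes read the human sequence was not tested.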

How the results depend on the processing

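Centring on neighbouring genes, the split of the controls, the stricter exon threshold and the variance weights were chosen after the data were seen. Of 5632 recomputed values of named genes 5118 kept direction and side of the threshold, 509 lost the call and 5 reversed. The cause of the reversals and moves below was not tested. Exceptions are gene-level counts lowered by fewer arrays and counts lowered by a minimum change. Fewer arrays do not account for the exon calls between the clones that rose when hIAPP a or rIAPP a was left out. Nor does the number of arrays alone account for the exon counts against control. Those fell more without control a, hIAPP a or rIAPP b than without the other array of that clone. When an array is left out its clone has 1 sample, assumed to vary like the other clones. Robust moderation of the list tests was not run. The number of arrays and signal near the range's ends limit the results.

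Leaving out 1 array gave 2001 to 2874 genes for hIAPP against control, 1224 to 2867 for rIAPP, 923 to 1780 between the clones, 781 to 1320 shared, 559 to 802 specific to hIAPP and 297 to 526 to rIAPP. Lists called between the clones were 1 to 2, and exon calls 179 to 692, 96 to 671 and 48 to 188. In the same order as the first 6 counts, medians of exon-level probe sets gave 1337, 953, 529, 507, 292 and 168, a minimum change of 1 gave 150, 108, 94, 54, 45 and 22, and a test against a change of 0.5 gave 246, 184, 124, 97, 63 and 33. An intensity trend gave 1137 genes specific to rIAPP, and 1 control array per contrast 745 or 760 shared genes. Of the 6, 5 and 2 lists called by camera, 0, 0 and 0 were called with an estimated correlation, and fry called 18, 14 and 8.

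Not counted among these, Iapp in rIAPP became called at 0.168 with an intensity trend or bright genes alone and at 0.174 after repeated quantile normalisation; between the clones it became called at −0.104 with the trend and −0.278 after neighbour centring, which reversed its hIAPP difference to −0.253; near the top of the range this cannot be read as a lower level. Neighbour centring also reversed Hspe1 (−0.0656) and Insig1 (−0.0132) in hIAPP and Ssr1 between the clones (−0.0540), and exon medians reversed Esam in rIAPP (−0.0232) and Gcgr between the clones (−0.00835).

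Exon calls between the clones were 273 without the filter. The Simes test gave 1067 in rIAPP and 195 between the clones, variance weights 2303, 2049 and 403, and an adjusted p under 0.001 gave 121, 95 and 29. With the sample letter as a replicate block 399 were called in rIAPP. The a minus b deviations of the clones correlated across genes at −0.0408, 0.000643 and 0.000376, so no shift shared by letter was seen. This does not tell whether samples with the same letter were handled together.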

Other observations

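Both tests of the signalling list were chosen only after the result was seen. The translocon and transport lists were drawn up after the chaperone result, but before their own values were seen. The fixed degradation and XBP1 list, already called in both clones, included related genes such as Sec61a1, Sec61b, Ssr1, Ssr3, Sec23b and Sec24d. The hypothesis was that the early secretory pathway was raised together with the ER chaperones. Of 32 measured translocon, signal peptidase and N-glycosylation genes 6 rose and none fell in hIAPP (mean 0.118, camera adjusted p = 0.000587), and 5 rose and none fell in rIAPP (mean 0.116, camera adjusted p = 0.000587). Of 31 COPI, COPII and ER-Golgi transport genes 7 rose and 1 fell in hIAPP (mean 0.0910, camera adjusted p = 0.0145), and 3 rose and 1 fell in rIAPP (mean 0.0868, camera adjusted p = 0.00693). All 4 results went as predicted, with means below the 0.34 and 0.38 of the chaperones. They come from the same arrays and follow calls of related genes, so they are not an independent test. With an estimated correlation all 4 had a camera adjusted p = 0.147, so the calls rest on the preset correlation. The state of the shared control clone stays open here as well. The translocon and transport lists were not tested on bright genes alone, without 1 array or after centring on neighbouring genes.

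A further hypothesis, that genes of G protein, cAMP and calcium signalling were lower as a group, did not pass its test without the genes seen before. It came from the largest falls, and of a list of 40 such genes 32 were measured. The mean was −0.221 in hIAPP (camera adjusted p = 0.185) and −0.293 in rIAPP (camera adjusted p = 0.0323; adjusted p = 0.159 with an estimated correlation). The list held 5 genes picked because their large changes had been seen, Gcgr, Gnat3, Gng3, Itpkb and Plch1, so this result says nothing about the group. Without them 5 of 27 genes were higher and 5 lower in hIAPP (mean −0.00793, camera adjusted p = 0.842). In rIAPP 2 were higher and 9 lower (mean −0.0879, camera adjusted p = 0.155). Without these 5 genes the list was called in neither clone, though more of its genes were lower than higher in rIAPP. That leaves a smaller fall there open. The genes taken out included large falls, so the test without them leans towards finding none.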
